A study of Mus musculus with 14 samples.

How the data were processed

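RNA abundance was measured by strand-specific sequencing of oligo(dT)-enriched mRNA, per the labels' protocols, in 14 libraries from clonally derived mouse bone marrow stromal cells. The deposited table holds whole-number read counts per gene, with 1 column per library and 23331 genes identified by Ensembl number and symbol. Columns were matched to libraries by the library names in the file header. Per the submitters' processing notes, CASAVA 1.8.0 and bedtools 2.11 were used with the mouse build mm9. The aligner, the filters on reads and the strand setting of the counting are not given in the sources used here. The counts of overlapping, antisense or near-identical genes are therefore uncertain, and 196 genes share their symbol with another gene in the table. Genomic coordinates are not reported, because the mouse annotation used for GC content follows a later build than mm9.

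Total counts ranged from 16888190 to 26076539 per library. Levels are given as CPM, the deposited counts scaled by TMM-adjusted library size. Intervals of single values are exact Poisson intervals at 95% and cover counting error only, since polymerase chain reaction copies were not identified.

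Libraries were grouped by the differentiation potential in their labels. The tripotent (OAC), osteo-adipogenic (OA), osteogenic (O) and adipogenic (A) groups hold 3 libraries each. Per the labels, numbers 1 and 2 are single clones from different mice, and number 3 is a pool of several other clones from those mice. The osteo-chondrogenic (OC3) and adipo-chondrogenic (AC3) pools have no replicate and entered none of the 7 comparisons below, although they have their own means in the fit.

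Genes with at least 1 CPM in at least 3 of the 14 libraries were tested, which left 13896 genes. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, robust dispersions and 6 group means. This gave 8 residual degrees of freedom, a common dispersion of 0.282 and prior degrees of freedom of 2.36 to 2.52. P values were adjusted by the Benjamini-Hochberg method within each of 7 comparisons (FDR, threshold 0.05). The comparisons were O vs A, OA vs O, OA vs A, OAC vs OA, OAC vs O, OAC vs A, and the multipotent groups (OAC and OA) vs the unipotent groups (O and A). A positive log2 fold change means a higher value in the group named first. The design, the gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined.

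DESeq2 1.42.0 (Wald test, same 6 means, default independent filtering) was the second test. An adjusted p was not given by DESeq2 for 21 genes, which were left out of its counts. Both tools were tested on simulated counts for O vs A, with the means, library sizes and 13896 genes of the real data and 200 genes changed. edgeR recovered 2, 16, 30 and 34 of the 50 genes changed by 2-, 4-, 8- and 16-fold, and 2 of its 84 calls were unchanged genes. DESeq2 recovered 8, 36, 41 and 45, and 61 of its 191 calls were unchanged genes, which is well above the nominal 5%. The counts came from a single draw, independent between genes, with the dispersions that edgeR had estimated. No GC trend of the libraries was built in, so these shares need not hold in the real data.

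Named genes had to pass the FDR, to average at least 5 CPM over the libraries compared and not to overlap between the groups. The genes with the greatest absolute log2 fold change were then taken, 10 per direction for O vs A, 8 for OA vs O, OA vs A and OAC vs OA, and 5 for the others. Predicted, unnamed and mitochondrial genes were passed over. The rule also names 11 lineage genes (Runx2, Sp7, Alpl, Bglap, Pparg, Cebpa, Fabp4, Lpl, Sox9, Acan, Col2a1) in every comparison, and up to 4 members with the lowest p of each list that was called. edgeR called at most 1 gene per comparison, so the same rule was also applied to the DESeq2 calls, a choice made after the edgeR result was seen. Genes so found whose DESeq2 call was lost when 1 library was left out are given with that library's value or passed over, which was also decided after the data were seen. Acan fell below the expression filter and was not tested.

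The 21 gene lists hold 405 genes, of which 386 are in the table. They cover the osteoblast, adipocyte and cartilage lineages, the marrow stromal niche, stromal surface markers, Hox genes, cell cycle, p53 targets, glucocorticoid response, Wnt feedback targets, secreted Wnt antagonists, BMP feedback targets, the Hedgehog and Notch pathways, interferon response, smooth muscle contractile genes and fibrillar matrix. Blood cell, endothelial, Schwann and neural, and skeletal muscle markers stand for other cell types, and so do the smooth muscle contractile genes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 21 lists. The test was repeated with an estimated correlation, and the fry test of limma was run beside it, also adjusted over the 21 lists. In simulated data camera called the list that was raised and 0 of the 20 others. Genes were drawn independently there, so the simulation cannot show how camera performs on lists with correlated members. In the real data the estimated correlation was 0.83 for the cell cycle list, 0.67 for the interferon list and 0.37 for the osteoblast list.

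GC content came from the longest transcript per Ensembl number and was found for 96.5% of tested genes. The first set of alternative settings held RLE factors, no filter or a filter at 5 CPM, DESeq2, a replicate block, only the groups compared, single clones only, an additive lineage model and each library left out in turn. For the axis from A to O, genes with at least a 4-fold change were also taken. Fits without OA2 and O1, GC offsets from a loess fit (span 0.4), alone and with the replicate block, limma voom with library weights, and the alternatives of the DESeq2 and list counts were added after the data were seen. All replicate pairs differed far beyond counting noise, with a chi-square per degree of freedom of 96.2 to 366, so no library was counted as a repeat of another.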

Results

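Gene expression was profiled by RNA sequencing in bone marrow stromal cells flushed from the femora and tibiae of adult C57Bl/6 mice. The mice carried a conditional large T antigen, a viral oncoprotein that keeps cells dividing while it is induced with dexamethasone and doxycycline. Clones were assayed for osteogenic (O), adipogenic (A) and chondrogenic (C) differentiation, and RNA was taken after 3 days without the inducers. The 14 libraries comprise 3 tripotent (OAC), 3 osteo-adipogenic (OA), 3 osteogenic (O) and 3 adipogenic (A) libraries and the pools OC3 and AC3. In each group of 3, numbers 1 and 2 are single clones and number 3 is a pool of clones. Single clones came from different mice, while a pool contains clones of the same 2 mice, so p-values measure the spread between these clones and pools. The labels do not state whether numbers 1 and 2 mark the same mouse in every group, so the replicate block need not be a block of mice. Total counts were 16888190 in OAC2, the shallowest library, to 26076539 in OC3, the deepest. Values are mean CPM ± SD over 3 libraries per group, log2 fold changes ± SE with FDR are from edgeR, and padj is the adjusted p of DESeq2. This SE was derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. It is not an SE given by the fit. In simulated data 61 of 191 DESeq2 calls were unchanged genes, so a padj alone is treated here as a weaker call than an FDR. Those data held no GC trend of the libraries.

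OA2 and O1 stood apart from the other libraries. Their deviation from the mean library followed GC content across genes with a Spearman rho of 0.65 and 0.51, and genes of low GC content lay at a median log2 deviation of -2.45 and -1.63. Other libraries followed GC content too. The rho was -0.54 in OAC3, OC3 and AC3, -0.47 in O2, -0.44 in O3, -0.43 in OA3, 0.35 in OAC1 and 0.36 in OAC2. The first principal component of log2 CPM held 43.3% of the variance, and its gene loadings correlated with GC content at a rho of -0.69. Markers of blood cells, endothelium, Schwann and neural cells and skeletal muscle were low throughout. Their summed level reached at most 70.2, 37.7, 97.5 and 83.6 CPM in this order. The osteoblast lineage list, which includes Col1a1 at up to 55600 CPM, summed to 17700 to 94800 CPM. Smooth muscle contractile markers were not low, at 8280 to 27400 CPM in sum, with Acta2 at up to 15600 CPM. Whether these reads came from another cell type was not tested.

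The first comparison asked what distinguishes osteogenic from adipogenic unipotent clones. Pitx1 (ENSMUSG00000021506), a homeobox transcription factor known for specifying the hindlimb, rose in O to 57.0 ± 43.1 CPM from 0.0409 ± 0.0411 CPM in A. The log2 fold change was 10.29 ± 0.95 with an FDR of 0.0076, and all 3 O libraries lay above all 3 A libraries. The A libraries held 3 Pitx1 reads together against 3314 in O, a ratio of 1240 with a 95% counting interval of 424 to 6010. Pitx1 was the only gene past the edgeR threshold among 13896, while 1374 genes had an unadjusted p under 0.05 and DESeq2 called 245 genes higher and 175 lower. Groups did not overlap for 15.6% of genes, where chance gives 10%.

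Bone matrix and osteoblast genes had higher means in O. Sp7 (ENSMUSG00000060284), the osteoblast transcription factor osterix, averaged 158 ± 208 CPM in O and 0.711 ± 0.284 CPM in A (7.78 ± 1.70, FDR 0.183, padj 1.07e-08). Ibsp, the bone sialoprotein, averaged 343 ± 424 and 0.292 ± 0.329 CPM (10.17 ± 3.03, FDR 0.304, padj 0.000126). Col1a1, the main collagen of bone, averaged 46190 ± 11170 and 8516 ± 3222 CPM (2.44 ± 0.39, FDR 0.123, padj 7.4e-08). Alkaline phosphatase (Alpl, 3.68 ± 1.13, FDR 0.322, padj 0.00637) and osteocalcin (Bglap, 4.53 ± 1.30, FDR 0.279, padj 0.00358) also had non-overlapping groups. Runx2, the master regulator of the lineage, averaged 129.5 CPM in O and 76.3 CPM in A and did not pass (0.76 ± 0.48, FDR 0.706, padj 0.552). As a set, the osteoblast lineage list rose in O (mean log2 difference 2.16, camera adjusted p 1.31e-09), although adjusted p = 0.311 with an estimated correlation. Of its 25 tested members 0 passed the FDR over all genes, and 12 higher and 1 lower passed when adjusted over the list alone. The lower member was Spp1, which encodes osteopontin and averaged 178 ± 43.9 CPM in O and 1034 ± 173 CPM in A (-2.54 ± 0.55, FDR 0.181). The spread within O was wide, since Ibsp stood at 1.85 CPM in O1, 817 in O2 and 209 in O3. Without O2 the DESeq2 log2 fold change was 5.80 for Sp7 (padj 0.000113), 8.51 for Ibsp (padj 0.0159), 1.97 for Alpl (padj 0.291) and 3.28 for Bglap (padj 0.148), and Alpl had a padj of 0.0586 without A2 and 0.054 without A3. The osteoblast mean was 1.43 without O2.

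Fat and marrow niche genes had higher means in A. Lpl (ENSMUSG00000015568), lipoprotein lipase, averaged 5.48 ± 5.59 CPM in O and 185 ± 66.4 CPM in A (-5.07 ± 1.04, FDR 0.166, padj 4.84e-06). Plin4, a lipid droplet coat protein, averaged 14.2 ± 14.8 and 399.8 ± 126 CPM (-4.81 ± 0.83, FDR 0.126, padj 1.62e-08). Pparg, the master regulator of fat cells, averaged 8.80 ± 3.49 and 39.3 ± 14.1 CPM (-2.16 ± 0.48, FDR 0.189, padj 0.00203, and 0.0586 without A2). Cebpa had -1.84 ± 0.57 (FDR 0.329, padj 0.076), and the fat cell marker Fabp4 did not pass (0.73 ± 0.85, FDR 0.942). The adipocyte lineage list fell in O (mean -0.87, adjusted p 0.00237, adjusted p = 0.311 with an estimated correlation), with 6 lower and 1 higher of 23 members adjusted over the list alone and 0 over all genes. The higher member was Fabp5, an epidermal-type fatty acid binding protein (3.46 ± 0.75, FDR 0.179, and 2.86 in DESeq2 without O2). Without O2 the adipocyte mean was -0.48. Cxcl12 (ENSMUSG00000061353), the chemokine that holds blood stem cells in the marrow, averaged 563 ± 141 CPM in O and 4126 ± 1491 CPM in A (-2.87 ± 0.37, FDR 0.0605, padj 7.48e-11). The marrow stromal niche list fell in O (mean -1.15, adjusted p 0.00059, adjusted p = 0.158 with an estimated correlation), with 3 lower of 16 members adjusted over the list alone and 0 over all genes.

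Other genes named by the rule had large differences that DESeq2 called and edgeR did not (FDR 0.123 to 0.333). Higher in O were Slc13a5, a citrate transporter (11.16 ± 3.43, padj 0.000501), Panx3, a channel of bone and cartilage cells (7.93 ± 2.49, padj 0.000156), Tnn, an extracellular matrix glycoprotein (7.64, padj 3.57e-06), Insc (7.58), Shank1 (7.20) and Gfra2 (6.76). Lower in O were Ms4a4d (-8.64 ± 1.38, padj 2.22e-11), the retinoic acid synthesis enzyme Aldh1a2 (-6.34 ± 1.76, padj 0.00104), the Wnt antagonist Sfrp1 (-5.81 ± 1.54, padj 0.000197), Adcyap1r1 (-7.28), S1pr3 (-4.97), Dpep1 (-4.91) and Mgst1 (-4.85). In DESeq2 Slc13a5 had 7.38 (padj 0.121) and Panx3 5.42 (padj 0.0575) without O2, and Aldh1a2 had -5.34 (padj 0.0587) without A2 and -5.78 without O2. The other genes of this paragraph kept the DESeq2 call whichever library was left out, although the log2 fold change was 5.80 for Tnn and 5.48 for Insc without O2, 6.65 for Shank1 and 5.37 for Gfra2 without O1, -7.26 for Ms4a4d without A2, -4.23 for Mgst1 without O2, and -4.73 for Sfrp1 and -3.91 for Dpep1 without A1.

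The cartilage list rose in O (mean 1.13, adjusted p 0.00237, adjusted p = 0.311 with an estimated correlation), with 5 higher and 1 lower of 14 members adjusted over the list alone and 0 over all genes. Its leading member was fibromodulin (Fmod, ENSMUSG00000041559), a collagen-binding proteoglycan also made by bone and tendon cells, at 378 ± 197 CPM in O and 22.6 ± 10.9 CPM in A (4.07 ± 0.53, FDR 0.0605, padj 9.24e-14). Comp and Fmod had higher means in O and the cartilage factor Sox5 a lower mean (-3.50 ± 0.63, FDR 0.142). Sox9 (0.61 ± 0.48, FDR 0.821) and Col2a1 (0.72 ± 1.17, FDR 0.995), the core cartilage genes, did not pass by either tool. The Hedgehog pathway list rose in O (mean 0.79, adjusted p 0.0286, adjusted p = 0.311 with an estimated correlation), with its receptor Ptch1 (1.74 ± 0.43) and its effector Gli1 (2.78 ± 0.89) among 3 members adjusted over the list alone. In DESeq2 Gli1 had 1.96 without O2 (padj 0.28) and a padj of 0.148 without A1 and 0.0573 without A2, and Ptch1 had 0.0672 without O2 and 0.059 without A2. The Wnt feedback targets list rose in O as well (mean 1.08, adjusted p 0.0424, adjusted p = 0.582 with an estimated correlation), with 0 of 13 members adjusted over the list alone. The interferon response list fell in O (mean -2.02, adjusted p 1.64e-09, adjusted p = 0.405 with an estimated correlation), and 24 of 24 members had lower means. Within A it ranged from -0.69 in A1 to 2.46 in A2, relative to the mean of 14 libraries. The cell cycle list fell in O (mean -0.86, adjusted p 8.48e-05, adjusted p = 0.665 with an estimated correlation), where O1 stood at -2.82, O2 at 0.72 and O3 at 0.20. For the interferon and cell cycle lists 0 members passed, over all genes or adjusted over the list alone. By the fry test only the niche list passed in O vs A (adjusted p 0.0212). The fry adjusted p was 0.0992 for the osteoblast, adipocyte and cartilage lists and 0.161 for Hedgehog. It was 0.182 for interferon and 0.488 for cell cycle and Wnt feedback targets.

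The other lists were not called by camera in O vs A. Their adjusted p was 0.199 for BMP feedback targets, 0.213 for Schwann and neural markers, 0.383 for blood cell markers, 0.445 for Hox genes, 0.703 for smooth muscle contractile genes and 0.974 for skeletal muscle markers. It was 0.648 for stromal surface markers, p53 targets, glucocorticoid response, secreted Wnt antagonists, the Notch pathway, fibrillar matrix and endothelial markers. In this group the mean and median differed in sign for stromal surface markers (0.46 and -0.07), secreted Wnt antagonists (-0.75 and 0.12) and endothelial markers (0.48 and -0.11), and for fibrillar matrix and p53 targets the mean and the test did (-0.08 and -0.06, test upward). For every list called in any comparison the mean, the median and the test had the same sign.

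Pitx1 kept a log2 fold change of 9.48 to 11.14 whichever library was left out, and its DESeq2 padj was at most 6.73e-10, but the edgeR FDR was 0.0766 without A1 (11.14) and 0.0759 without A2 (10.29). Other calls depended on single libraries. The count of edgeR calls was 2 without O1, 4 without O3 and 3 without A3, DESeq2 called 241 genes without O1, 274 without O2, 264 without A1 and 244 without A2, and camera called 5 lists without O2. Without O1 the cell cycle mean was 0.24 (adjusted p 0.879), and without O2 it was -1.53. The adipocyte list had an adjusted p of 0.154 without O2, the interferon mean was -1.27 without A2 (adjusted p 7.93e-05), and the niche list had 0.0937 without OA2 and O1. The Hedgehog list had 0.0908 without O2, 0.0842 without O3, 0.184 without A2 and 0.0663 without A3, and the Wnt list had 0.169, 0.212, 0.296 and 0.0832 (mean 0.54 without A2).

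**Figure D1:**
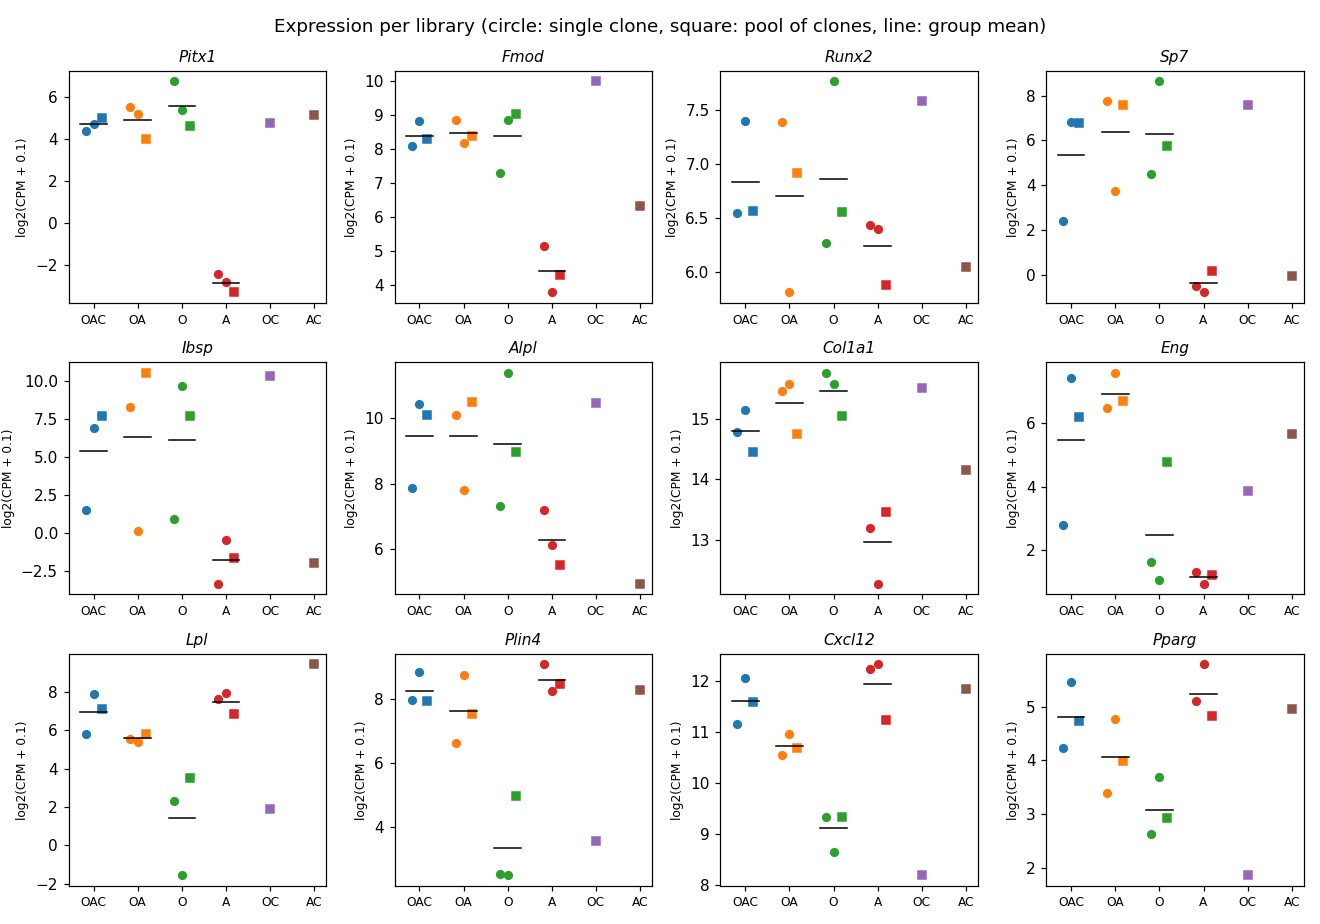
Expression of 12 genes in each library, as log2 of CPM with a small constant added (vertical axis, a separate log scale per gene) by group (horizontal axis), with circles for single clones in the order 1 and 2, squares for pools and a line for the mean of each group of 3. Pitx1 was at most 0.08 CPM in the A libraries and at least 15.7 CPM in the other 11 libraries.

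The comparison of OA with O asked what accompanies adipogenic potential added to osteogenic potential. Fat and niche genes again had higher means in the group with adipogenic potential. Plin4 averaged 237 ± 169.9 CPM in OA and 14.2 ± 14.8 CPM in O (4.06 ± 0.80, FDR 0.851, padj 4.81e-05), and Lpl averaged 47.9 ± 7.55 and 5.48 ± 5.59 CPM (3.12 ± 0.95, FDR 0.851, padj 0.0694). The preadipocyte factor Zfp423 had 2.79 ± 0.69 (padj 0.018), and Cxcl12 averaged 1710 ± 263 CPM against 563 ± 141 CPM (1.60 ± 0.35, padj 0.0159). Ret, a receptor tyrosine kinase, averaged 142 ± 171 and 5.51 ± 3.67 CPM (4.67 ± 0.97, padj 4.81e-05). Srpx was lower in OA (-4.98 ± 0.98, padj 1.13e-05). Of the 18 genes named from the DESeq2 calls in OA vs O, only Plin4, Ret and Srpx kept the call whichever library was left out, and without OA2 the log2 fold change was 3.32 for Plin4 and 2.94 for Ret. Zfp423 had a padj of 0.385 without OA2 and 0.061 without O2, and Cxcl12 had 0.268 and 0.0789. The osteogenic genes Sp7 (-0.17 ± 1.24), Alpl (-0.27 ± 1.01), Runx2 (-0.17 ± 0.48) and Bglap (-1.35 ± 1.12) did not pass by either tool, nor did Pparg (1.02 ± 0.47), Cebpa (1.43 ± 0.57), Fabp4 (-1.22 ± 0.86), Sox9 (0.06 ± 0.48) or Col2a1 (-0.26 ± 1.17).

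By edgeR 0 genes passed in OA vs O, with 755 at an unadjusted p under 0.05, and DESeq2 called 27 higher and 15 lower. Groups did not overlap for 8.20% of genes, against 10% by chance. The adipocyte list rose in OA (mean 0.85, adjusted p 0.000193, with 2 of 23 members adjusted over the list alone), as did the niche list (0.58, 0.0111, with 2 of 16), the interferon list (1.32, 1.25e-06), the cell cycle list (0.76, 1.25e-06) and the fibrillar matrix list (0.52, 0.0238), and the p53 targets fell (-0.63, 0.0235), the last 4 with 0 members. With an estimated correlation the adjusted p = 0.33 for the adipocyte and niche lists, 0.551 for interferon and p53 targets, 0.677 for cell cycle and 0.47 for fibrillar matrix. Beside these lists stand the library O1, at -2.82 for cell cycle, and OA2, at -0.79. Without O1 the cell cycle mean was -0.34 with an adjusted p of 0.799, and the adjusted p was 0.41 for the niche list, 0.718 for p53 targets and 0.224 for fibrillar matrix, the niche list had 0.0595 without OA3, p53 targets had 0.253 without OA1, and fibrillar matrix had 0.596, 0.166 and 0.0729 without OA2, OA3 and O2. DESeq2 called 9 genes without OA2, 304 without OA3, 16 without O1 and 117 without O3, and camera called 2 lists without O1. Without O2 the mean was 0.45 for the adipocyte list and 0.73 for interferon, which had 2.01 without O3. The niche mean was 0.22 without O1 and 0.95 without O3, that of p53 targets -0.39 without OA2, and that of cell cycle 0.35, 1.18, 1.43 and 1.17 without OA1, OA2, O2 and O3.

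The comparison of OA with A asked what accompanies osteogenic potential added to adipogenic potential. Pitx1 rose again, at 32.4 ± 15.3 CPM in OA (9.47 ± 0.93, FDR 0.0137), a ratio of 795 over A (272 to 3860). It was the only gene past the edgeR threshold, with 733 genes at an unadjusted p under 0.05, and DESeq2 called 91 higher and 39 lower. Osteoblast genes had higher means, with Sp7 at 141 ± 111 CPM (7.61 ± 1.69, FDR 0.649, padj 1.1e-07), Ibsp at 612 ± 802 CPM (11.01 ± 3.11, padj 4.19e-05), Alpl at 924 ± 629 CPM (padj 0.0352, against 87.3 ± 52.4 CPM in A, but 0.2, 0.173, 0.212 and 0.197 without OA1, OA3, A2 and A3) and Col1a1 at 40670 ± 11380 CPM (2.26 ± 0.39, padj 3.63e-06). Endoglin (Eng), a co-receptor of TGF-beta used as a stromal surface marker, averaged 128 ± 56.4 CPM in OA and 2.15 ± 0.293 CPM in A (5.89 ± 1.31, FDR 0.649, padj 4.07e-06). Eng did not follow osteogenic potential across the libraries, with 2.99, 1.99 and 27.2 CPM in O1, O2 and O3 and 51.1 CPM in AC3. Panx3 (8.29) and Tspan18 (5.30) were also higher. Lower in OA were Smoc1 (-3.20) and Adcyap1r1 (-4.81), whose padj was 0.114 without A2. Of the 25 genes named from the DESeq2 calls in OA vs A, 11 kept the call whichever library was left out. Without OA3 the DESeq2 log2 fold change was 9.09 for Ibsp and 6.93 for Panx3, and Smoc1 had -2.52 without A3. Pparg (-1.14 ± 0.47), Lpl (-1.95 ± 0.90), Cebpa (-0.41 ± 0.56), Fabp4 (-0.49 ± 0.85), Bglap (3.19 ± 1.24), Runx2 (0.59 ± 0.48), Sox9 (0.67 ± 0.48) and Col2a1 (0.46 ± 1.17) did not pass by either tool.

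In OA vs A the osteoblast list rose (mean 2.16, adjusted p 2.67e-13, 10 of 25 members higher adjusted over the list alone), as did cartilage (0.86, 0.00906, with 5 higher and 1 lower of 14), fibrillar matrix (0.44, 0.00326, with 4 of 24) and Hedgehog (0.58, 0.0342, with 2 of 9). None of these members passed the FDR over all genes, and for each of the 4 lists the adjusted p = 0.332 with an estimated correlation. Among the fibrillar matrix members were Col12a1 (1.31 ± 0.31), Col3a1 (2.80 ± 0.71) and Col6a3 (1.46 ± 0.37). In DESeq2 Col12a1 had a padj of 0.0551 and 0.0645 without OA2 and OA3, Col3a1 had 2.22 without OA2 (padj 0.111) and a padj of 0.0973 and 0.0563 without A2 and A3, and Col6a3 had 0.97 without OA2 (padj 0.18) and a padj of 0.215 and 0.162 without A1 and A3. Groups did not overlap for 717 genes higher and 807 lower in OA among the 13896 tested, where chance gives 10%. Pitx1 kept a log2 fold change of 8.92 to 10.33 whichever library was left out, and its DESeq2 padj was at most 4.94e-08, but the edgeR FDR was 0.124, 0.249, 0.111 and 0.0518 without A1, A2, A3 and OA1. DESeq2 called 74 genes without OA1, 84 without A1 and 78 without A2, and camera called 8 lists without OA2 and 2 without OA3. The adjusted p was 0.269 for cartilage without OA3, 0.113 for fibrillar matrix without OA2, and 0.243, 0.0947, 0.24 and 0.0793 for Hedgehog without OA1, OA3, A2 and A3. Means were 0.48 for cartilage without OA3, 0.38 and 0.31 for Hedgehog without OA1 and A2, and 0.68, 0.29 and 0.27 for fibrillar matrix without OA1, OA2 and A2.

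The comparison of OAC with OA asked what accompanies chondrogenic potential, and no gene or list passed. edgeR and DESeq2 both called 0 genes, with 163 at an unadjusted p under 0.05 by edgeR, and groups did not overlap for 4.93% of genes, against 10% by chance. Sox9 averaged 13.6 ± 5.60 CPM in OAC and 20.1 ± 7.31 CPM in OA (-0.56 ± 0.48, FDR 1), and Col2a1 averaged 119.8 ± 113 and 126 ± 135 CPM (-0.08 ± 1.17, FDR 1). Acan, the main proteoglycan of cartilage, was at most 0.67 CPM in any of these 6 libraries. The cartilage list had a mean of 0.01 (adjusted p 0.895), and the lowest adjusted p among all lists was 0.182. Lpl averaged 143 ± 90.7 CPM in OAC and 47.9 ± 7.55 CPM in OA without overlap (1.58 ± 0.89, FDR 1). The margin was narrow, with 56.44 CPM in OAC1 and 56.1 CPM in OA3. The other lineage genes lay between -0.88 ± 1.25 for Sp7 and 1.00 ± 0.85 for Fabp4. DESeq2 called 4 genes without OAC1, 2 without OAC2, 2 without OAC3 and 13 without OA3, and camera called 3 lists without OAC2, 2 without OAC3, 8 without OA2 and 1 without OA3.

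The comparison of OAC with O contrasted tripotent with osteogenic clones. Fat and niche genes had higher means in OAC. Lpl averaged 143 ± 90.7 CPM against 5.48 ± 5.59 CPM (4.70 ± 1.02, FDR 0.73, padj 0.000208), Plin4 320.1 ± 122 against 14.2 ± 14.8 CPM (4.49 ± 0.81, padj 1.03e-06) and Pparg 29.6 ± 12.9 against 8.80 ± 3.49 CPM (1.75 ± 0.47, padj 0.0478, but 0.502, 0.116, 0.3 and 0.151 without OAC2, OAC3, O1 and O3). Cxcl12 averaged 3195 ± 983 against 563 ± 141 CPM (2.50 ± 0.36, FDR 0.462, padj 1.65e-07), and Spp1 had 2.76 ± 0.56 (padj 0.000386). Sfrp1 (5.39), Dpep1 (5.09) and Ret (4.15) were also higher by DESeq2. Lower in OAC were podoplanin (Pdpn, a membrane glycoprotein, -7.46 ± 2.03, padj 0.00296) and the sialomucin Cd34 (-5.19). Of the 13 genes named from the DESeq2 calls in OAC vs O, 6 kept the call whichever library was left out, namely Lpl, Plin4, Cxcl12, Spp1, Dpep1 and Ret. Without OAC2 the DESeq2 log2 fold change was 2.13 for Spp1, 4.36 for Dpep1 and 3.51 for Ret, without OAC1 it was 4.20 for Sfrp1 (padj 0.114), and without O1 -6.68 for Pdpn (padj 0.0799) and -3.06 for Cd34 (padj 0.146). Sp7 (-1.05 ± 1.26), Alpl (-0.30 ± 1.01), Runx2 (-0.12 ± 0.47), Bglap (-1.17 ± 1.12), Cebpa (1.52 ± 0.57), Fabp4 (-0.22 ± 0.84), Sox9 (-0.49 ± 0.48) and Col2a1 (-0.34 ± 1.17) did not pass by either tool.

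By edgeR 0 genes passed in OAC vs O, with 836 at an unadjusted p under 0.05, and DESeq2 called 69 higher and 32 lower. Groups did not overlap for 11.5% of genes, against 10% by chance. The adipocyte list rose in OAC (mean 0.89, adjusted p 7.09e-05, with 3 of 23 members adjusted over the list alone), as did the niche list (0.87, 0.000223, with 2 of 16), cell cycle (0.66, 0.000133), interferon (0.90, 0.00169) and fibrillar matrix (0.43, 0.038), the last 3 with 0 members. With an estimated correlation the adjusted p = 0.214 for adipocyte, 0.106 for niche, 0.552 for cell cycle and interferon, and 0.469 for fibrillar matrix. Without O1, which stood at -2.82, the cell cycle list had a mean of -0.43 (adjusted p 0.357), interferon had 0.106 without OAC3 and 0.466 without O2, and fibrillar matrix had 0.327 without OAC1 and 0.163 without O2. DESeq2 called 64 genes without OAC1, 28 without OAC2, 36 without O1 and 185 without O3, and camera called 11 lists without OAC2. Without O2 the mean was 0.49 for the adipocyte list, 1.34 for cell cycle, 0.31 for interferon and 0.28 for fibrillar matrix. It was 0.52 for the niche list without O1, 0.31 and 1.08 for cell cycle without OAC3 and O3, 1.59 for interferon without O3 and 0.24 for fibrillar matrix without OAC1.

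The comparison of OAC with A contrasted tripotent with adipogenic clones. Pitx1 rose here as well, at 25.9 ± 5.44 CPM in OAC (9.15 ± 0.92, FDR 0.0176), a ratio of 656 (224 to 3180) over the same 3 A libraries as in the comparisons of O and OA, so these 3 results are not independent. It was the only gene past the edgeR threshold, with 498 genes at an unadjusted p under 0.05, and DESeq2 called 50 higher and 7 lower. Sp7 averaged 76.3 ± 61.6 CPM (6.73 ± 1.63, FDR 1, padj 1.27e-05), Ibsp 112 ± 103 CPM (8.55 ± 2.87, padj 0.0107, but 0.142, 0.155 and 0.0812 without OAC2, OAC3 and A3) and Fmod 342 ± 95.2 CPM (3.92 ± 0.52, FDR 0.118, padj 1.09e-12). Lower in OAC were the keratinocyte envelope gene Sprr1a (-9.71 ± 2.45, padj 0.00117), most of whose reads came from A3 at 49.5 CPM (padj 0.321 without A3), and the kinetochore gene Zwint, at 97.9 ± 6.64 against 169 ± 20.2 CPM (-0.78 ± 0.16, padj 0.000435). Of the 16 genes named from the DESeq2 calls in OAC vs A, 5 kept the call whichever library was left out, among them Pitx1, Sp7, Fmod and Zwint. Lpl (-0.37 ± 0.87), Pparg (-0.41 ± 0.46), Cebpa (-0.32 ± 0.56), Fabp4 (0.51 ± 0.84), Alpl (3.38 ± 1.11), Bglap (3.36 ± 1.25), Runx2 (0.64 ± 0.48), Sox9 (0.11 ± 0.48) and Col2a1 (0.38 ± 1.17) did not pass by either tool.

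In OAC vs A the osteoblast list rose (mean 1.78, adjusted p 6.03e-13, with 4 of 25 members adjusted over the list alone), as did cartilage (0.87, 0.00379, with 2 of 14), fibrillar matrix (0.35, 0.000593, with 3 of 24), Hedgehog (0.40, 0.0129) and Wnt feedback targets (0.96, 0.0131), and interferon fell (-1.12, 2.17e-05), the last 3 with 0 members. With an estimated correlation the adjusted p = 0.247 for osteoblast, cartilage, Hedgehog and fibrillar matrix, 0.521 for Wnt feedback targets and 0.643 for interferon. Groups did not overlap for 10.8% of genes, against 10% by chance. Whichever library was left out, Pitx1 had a log2 fold change of 8.60 to 10.00 and a DESeq2 padj of at most 2.18e-07, but the edgeR FDR was 0.0583, 0.0707 and 0.0639 without OAC1, OAC2 and OAC3 and 0.151, 0.307 and 0.139 without A1, A2 and A3. DESeq2 called 106 genes without OAC1 and 14 without OAC2, and camera called 3 lists without OAC1. Without OAC1 the adjusted p was 0.0994 for interferon and fibrillar matrix and 0.107 for Hedgehog, without A2 it was 0.281 for interferon and Wnt feedback targets and 0.233 for Hedgehog, and without OAC2 it was 0.0633 for Wnt feedback targets. Means were 0.63 and 0.42 for Wnt feedback targets without OAC2 and A2, 0.67 and 0.14 for Hedgehog without A1 and A2, -0.68, -1.94 and -0.37 for interferon without OAC1, A1 and A2, and 0.16, 0.54 and 0.17 for fibrillar matrix in the same order.

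The last comparison set the multipotent groups (OAC and OA, 6 libraries) against the unipotent groups (O and A, 6 libraries). Col6a3, a chain of collagen VI, averaged 3881 ± 1231 CPM against 1744 ± 592 CPM (1.18 ± 0.26, FDR 0.998, padj 0.0163), with every multipotent library above every unipotent library, although the padj was 0.0982, 0.0634, 0.0534, 0.06 and 0.115 without OAC2, OAC3, O3, A1 and A3. The margin was narrow, with 2621 CPM in OA3 and 2599 CPM in O2. The pools OC3 and AC3, outside the comparison, stood at 2368 and 4222 CPM of Col6a3. Zwint was lower (95.7 ± 7.44 against 151 ± 23.4 CPM, -0.65 ± 0.11, FDR 0.854, padj 1.12e-06), the only 1 of 7 genes named from the DESeq2 calls in this comparison that kept the call whichever library was left out. Zwint stood at 81.35 CPM in OC3 and 109.04 CPM in AC3, and the lowest unipotent library was O1 at 129.18 CPM. The pools have no replicate, so these are values with no test. By edgeR 0 genes passed, with 676 at an unadjusted p under 0.05, and DESeq2 called 23 higher and 8 lower. Groups did not overlap for 0.288% of genes, where chance gives 0.216%. Of the lineage genes Sp7 passed by DESeq2 (3.28 ± 0.98, FDR 0.998, padj 0.025), although its mean in the unipotent group joined 158 CPM in O with 0.711 CPM in A. Its padj was 0.167, 0.109, 0.102, 0.0523, 0.0713, 0.0673, 0.0928 and 0.0541 without OAC2, OAC3, OA1, O1, O3, A1, A2 and A3. Alpl (1.55 ± 0.73), Lpl (1.38 ± 0.63), Pparg (0.30 ± 0.33), Runx2 (0.23 ± 0.34), Bglap (1.01 ± 0.81), Cebpa (0.55 ± 0.39), Fabp4 (-0.35 ± 0.60), Sox9 (0.09 ± 0.34) and Col2a1 (0.06 ± 0.83) did not pass.

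Across the multipotent and unipotent libraries the fibrillar matrix list rose (mean 0.44, adjusted p 3.8e-05, with 1 of 24 members adjusted over the list alone), as did the osteoblast (0.89, 2.81e-06), adipocyte (0.43, 0.000875) and cell cycle lists (0.28, 0.00184), and p53 targets fell (-0.54, 0.00498), the last 4 with 0 members. With an estimated correlation the adjusted p = 0.276 for fibrillar matrix, 0.332 for osteoblast, adipocyte and p53 targets, and 0.659 for cell cycle. The osteoblast, adipocyte and cell cycle means each came from 1 unipotent group. OA and OAC differed from A by 2.16 and 1.78 for osteoblast genes and from O by 0.01 and -0.38, while they differed from O by 0.85 and 0.89 for adipocyte and 0.76 and 0.66 for cell cycle genes and from A by -0.02 and 0.01 and by -0.10 and -0.19. Without O1, at -2.82 for cell cycle, the cell cycle list had a mean of -0.27 (adjusted p 0.797), and it had 0.0882 without OAC3 (mean 0.10) and 0.0703 without OA1 (mean 0.08), with means of 0.51, 0.62 and 0.49 without OA2, O2 and O3. The osteoblast mean was 0.52 without O1 and the adipocyte mean 0.23 without O2. The p53 targets had an adjusted p of 0.0804, 0.0619, 0.395 and 0.0536 without OAC3, OA1, O1 and A3, camera called 3 lists without OAC3 or O1 and 8 without O3, and DESeq2 called 82, 15, 141, 87 and 16 genes without OAC1, OAC2, OA3, O2 and A3.

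**Figure D2:**
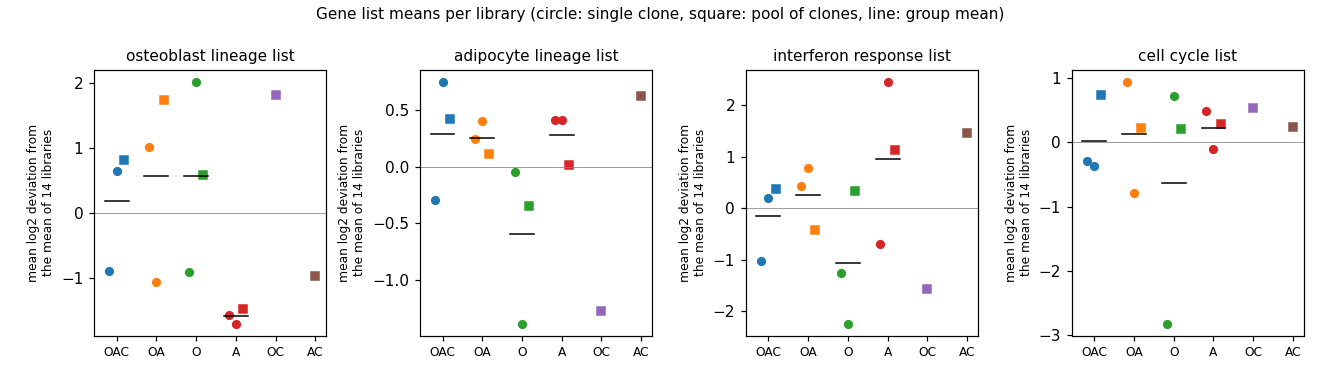
Mean log2 CPM deviation from the mean of the 14 libraries (vertical axis) over the members of the osteoblast, adipocyte, interferon and cell cycle lists in each library by group (horizontal axis), with circles for single clones, squares for pools and a line for the mean of each group of 3. The A libraries lie between -1.71 and -1.49 on the osteoblast list, and O1 lies at -2.82 on the cell cycle list.

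The pools OC3 and AC3 were placed on the axis from A (0) to O (1), which as designed used the genes that edgeR called in O vs A and so rested on Pitx1 alone. OC3 stood at 0.90 and AC3 at 0.95, with 26.7 and 34.2 CPM of Pitx1. Over the 420 genes called by DESeq2, a choice added after the data were seen, OC3 stood at 0.94 and AC3 at 0.21, the OA libraries at 0.39 to 0.69 and the OAC libraries at 0.34 to 0.55. In AC3, Sp7 stood at 0.873 CPM (0.711 CPM on average in A) and Cxcl12 at 3672 CPM (2413 to 5131 CPM in A), while Lpl at 693 CPM and Sox9 at 24.4 CPM were above all A libraries (at most 246 and 18.7 CPM). In OC3, Sp7 stood at 192 CPM, Lpl at 3.68 CPM and Cxcl12 at 291 CPM. These pools have no replicate, so the values describe these libraries.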

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

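The pools OC3 and AC3 enter none of the 7 comparisons, and the 11 lineage genes were searched there for levels above all 12 replicated libraries beyond counting error.

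Lpl, lipoprotein lipase, stood at 693 CPM in AC3 (95% counting interval 683 to 703, 17467 reads), where the highest of the 12 replicated libraries was A2 at 246 CPM. Acan, the main cartilage proteoglycan, stood at 5.99 CPM in OC3 (5.09 to 7.00, 158 reads), where the highest of the 12 was OA3 at 0.673 CPM with 15 reads. The intervals cover counting error only, and neither pool has a replicate.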

How the results depend on the processing

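The alternatives without OA2 and O1, with GC content, with voom weights and those of the DESeq2 and list counts were chosen after the data were seen. Of the list means of the lists called, 298 kept direction and call, 99 lost the call and 7 reversed. Among the named genes edgeR called only Pitx1, in 3 comparisons, where over the alternatives 32 of its values kept the call and 22 lost it. The other genes were counted only with RLE factors, the changed filters, DESeq2, the replicate block, single clones only, GC offsets and without OA2 and O1. Fits with 1 library left out are not in their counts. Of their values 1912 stayed in direction and without a call, 122 gained a call and 29 reversed. Of the 122, 114 were gained in DESeq2. The cause was not tested where none is given. Deviations of libraries sharing a replicate number correlated at -0.31 to 0.39 for number 1 (4 of 6 pairs over 0.1), -0.58 to 0.47 for number 2 (1 of 6) and 0.29 to 0.76 for number 3 (6 of 6), so the pools (number 3) resembled each other and numbers 1 and 2 did not pair in this way, and 7 of 12 libraries correlated best with their own number. With the replicate block edgeR called 1 gene in O vs A, OA vs A and OAC vs A and 0 in the other comparisons, as without it, and all 34 list calls were kept.

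The edgeR count was unchanged in all 7 comparisons with RLE factors and the 5 CPM filter. Without a filter it was 2 in O vs A, 2 in OA vs A and 2 in OAC vs A, in each case Pitx1 and Fmod. With only the groups compared it was 0 in O vs A, 0 in OA vs A and 2 in OAC vs A (Pitx1 and Clec11a), and with single clones only 0 in these 3 comparisons, where fewer libraries were fitted. The additive lineage model called 65 genes in O vs A, without Pitx1, 0 in OA vs A and 0 in OAC vs A. Without OA2 and O1 edgeR called 3 in O vs A (Pitx1, Fmod and Clec11a), 2 in OA vs A and 2 in OAC vs A. With GC offsets it called 5 in O vs A (Pitx1, Cxcl12, Igdcc4, Col1a1 and Cldn15) and 1 in multipotent vs unipotent (Pitx1). When the replicate block was added to the GC offsets, Pitx1 was the only call in O vs A, OA vs A and OAC vs A. Multipotent vs unipotent then had 0 calls (lowest FDR 0.0645). Voom with library weights, which were 0.22 for OA2, 0.20 for O1 and 4.07 for O3, called 151 in O vs A with Pitx1 among them, and 1 gene in OA vs A and 1 in OAC vs A, which was Fmod and not Pitx1. DESeq2 called 420 in O vs A, 42 in OA vs O, 130 in OA vs A, 101 in OAC vs O, 57 in OAC vs A and 31 in multipotent vs unipotent. For Pitx1 in O vs A the edgeR and voom alternatives and DESeq2 with all libraries gave an adjusted p of 1.91e-20 to 0.404 and a log2 fold change of 4.16 in the additive model and 9.41 to 11.14 in the others, and DESeq2 with 1 library left out gave 9.67 to 11.57 (padj 2.94e-22 to 6.73e-10). In the additive model it was 2.99 in OA vs A and 4.84 in OAC vs A.

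Which direction held more DESeq2 calls in O vs A depended on the libraries. It was 213 higher and 276 lower without OA2 and O1, 265 and 315 without O3, and 171 and 179 with single clones only. With GC factors it was 309 and 263, and with the block 311 and 243. Without OA2 and O1, 271 of the 420 genes were called again in the same direction. With single clones only, where fewer libraries were fitted, 232 of the 420 were called again in this way. The other comparisons then kept 24 of 42 in OA vs O, 33 of 130 in OA vs A and 46 of 101 in OAC vs O. OAC vs A kept 12 of 57 and multipotent vs unipotent 11 of 31. Of the DESeq2 counts, that of OA vs O was 9 without OA2 and O1, 74 with GC factors, 76 with the replicate block and 130 with single clones only. OA vs A had 220 without OA2 and O1 and 56 with single clones, OAC vs OA had 1, 2, 4 and 4 without OA2 and O1, with GC factors, with the block and with single clones, OAC vs O had 153 with GC factors and 167 with the block, OAC vs A had 91 without OA2 and O1 and 26 with single clones, and multipotent vs unipotent had 55 with GC factors and 58 with the block.

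With an estimated correlation camera called 0 lists in O vs A, OA vs O, OA vs A, OAC vs O, OAC vs A and multipotent vs unipotent. With single clones only it called 1 in OA vs A and 2 in OAC vs OA. Without OA2 and O1 it called 5 in O vs A, 2 in OA vs O, 8 in OA vs A, 8 in OAC vs OA and 3 in multipotent vs unipotent, and after GC adjustment 2 in OAC vs OA. By the fry test the niche list in O vs A was the only list that passed in any comparison (adjusted p 0.0212). The lowest fry adjusted p was 0.416 in OA vs O, 0.26 in OA vs A and 0.97 in OAC vs OA. It was 0.0933 in OAC vs O, 0.344 in OAC vs A and 0.381 in multipotent vs unipotent. On the axis from A to O, AC3 moved from 0.95 to 0.21 with the genes called by DESeq2, which replace Pitx1 alone by 420 genes.

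Leaving out 1 library at a time, the edgeR count ranged from 0 to 4 in O vs A, from 0 to 1 in OA vs A and was 0 throughout in OAC vs A. The DESeq2 count ranged from 241 to 580 in O vs A, 9 to 304 in OA vs O, 74 to 183 in OA vs A, 0 to 13 in OAC vs OA, 28 to 185 in OAC vs O, 14 to 106 in OAC vs A and 15 to 141 in multipotent vs unipotent. The number of lists ranged from 5 to 8, 2 to 7, 2 to 8, 0 to 8, 4 to 11, 3 to 7 and 3 to 8 in the same order.

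The reversed fold changes were of genes that passed neither tool in that comparison. With the replicate block they were Sp7 (0.78) and Alpl (0.26) in OA vs O, Runx2 (-0.05), Bglap (-0.31) and Col2a1 (0.70) in OAC vs OA and Col2a1 in OAC vs O (0.51). With single clones only they were Sox9 (-0.25) and Col2a1 (0.99) in OA vs O, Alpl (0.35), Cebpa (-0.05) and Col2a1 (0.15) in OAC vs OA, Col2a1 in OAC vs O (1.14), and Sox9 in OAC vs A (-0.17) and multipotent vs unipotent (-0.21). Without OA2 and O1 they were Sox9 in OA vs O (-0.18), Fabp4 (0.01) and Col2a1 (-0.85) in OA vs A, Runx2 (-0.27), Bglap (-0.21) and Col2a1 (1.26) in OAC vs OA, and Pparg (0.00), Sox9 (-0.03) and Col2a1 (-0.82) in multipotent vs unipotent. In OAC vs OA Alpl was 0.02 with RLE factors, 0.02 in DESeq2 and 0.02 with GC offsets, which also reversed Col2a1 in OAC vs OA (0.03) and multipotent vs unipotent (-0.22) and Vcam1 in OA vs O (0.19). The cell cycle mean was 0.22 in O vs A, -0.40 in OAC vs O and -0.02 in multipotent vs unipotent without OA2 and O1, and 0.24 in O vs A, -0.34 in OA vs O, -0.43 in OAC vs O and -0.27 in multipotent vs unipotent without O1. Leaving out 1 library at a time, the cell cycle mean reached -1.53, 1.43, 1.34 and 0.62 in these 4 comparisons, each without O2.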

Other observations

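The tests of GC content and depth for Pitx1, the use of the DESeq2 calls, the splits with 2 pools on each side and the genes named next for OC3 and AC3 were chosen after the results were seen. OC3 had the highest mean of all 14 libraries on the cartilage list (1.36 above their mean on the log2 scale) and on the Hedgehog list (1.26), with an osteoblast mean of 1.82 and an interferon mean of -1.57. Hhip, a Hedgehog target that binds Hedgehog ligands, stood at 46.5 CPM in OC3 and at most 5.74 CPM in the other libraries, and the ligand Ihh at 8.30 and at most 4.67 CPM. The cartilage factor Sox6 stood at 11.5 CPM in OC3 and at most 4.10 CPM elsewhere, and Fmod at 1010 and at most 523 CPM.

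AC3 had the highest mean of the 14 libraries on the niche list (1.04) and the fibrillar matrix list (0.86), and the lowest on the Wnt feedback list (-1.97). The adhesion molecule Vcam1 stood at 211 CPM in AC3 and at most 92.8 CPM elsewhere, and Emb at 62.3 and at most 32.2 CPM. OC3 and AC3 are single pools, so these are values of those libraries with no test. Both pools followed GC content at a rho of -0.54, and these levels were not adjusted for it.

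Pitx1 was near zero in the A libraries and present in every other library, AC3 included at 34.2 CPM. At the lowest level among the other 11 libraries 1180 reads would be expected in the 3 A libraries, against 3 seen, which argues against depth, and with GC offsets the log2 fold change in O vs A was 10.16 (FDR 0.000569, with 1.91e-20 to 0.404 over the alternatives and 2.94e-22 to 6.73e-10 in DESeq2 with 1 library left out), which argues against the GC trend. The explanation that the A clones lacked hindlimb identity as a whole was set beforehand to predict lower Tbx4 and posterior Hox genes in A. How far these Hox genes mark the hindlimb was not tested. The 11 tested genes of paralog groups 9 to 13 had a mean difference of -0.34 ± 0.62 (SE over genes), 5 higher and 6 lower in O. Among them DESeq2 called only Hoxc11, at 17.73 ± 11.75 CPM in O and 1.20 ± 1.54 CPM in A (3.88 ± 1.21, FDR 0.329, padj 0.00979). The mean over the 11 genes met the bound set beforehand against the explanation, yet members going both ways decide nothing. Tbx4, with at most 3 reads in a library, was not tested. What the low level in A goes with, adipogenic unipotency or the descent of these clones, stays open, as no test here addresses it. Per the labels A1 and A2, at 0.08 and 0.04 CPM, are clones of different mice, so descent from a single founder cell is not among the possibilities.

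The cell cycle and interferon lists were both lower in O than in A. After GC adjustment the cell cycle difference was 0.92 of its value (adjusted p 0.000108) and the interferon difference 0.96 (adjusted p 1.95e-09), which argues against the GC trend for both. Without O1 the cell cycle difference was -0.28 of its value (adjusted p 0.879, from 8.48e-05 in the fit of all libraries), so it rested on O1, and the interferon difference was 0.95 of its value (adjusted p 2.3e-07), which argues against O1 as its source. The interferon means were -1.25, -2.24 and 0.33 in O1, O2 and O3 and -0.69, 2.46 and 1.13 in A1, A2 and A3, so O3 lay above A1. The groups did not overlap for 4 of 24 members, against 15.6% of all genes. Whether a difference between osteogenic and adipogenic clones underlies the interferon list stays open, and its call was lost with an estimated correlation (adjusted p = 0.405). Differences between clones in growth or in innate immune activity within a group, where A1 stood at -0.69 and A2 at 2.46, stay open as untested.

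DESeq2 called 420 genes in O vs A where edgeR called 1. With GC normalization factors 0.89 of these genes (373 of 420) were called again in the same direction, which argues against the GC trend as the cause. In simulated data for this comparison 61 of 191 DESeq2 calls and 2 of 84 edgeR calls were unchanged genes, so part of the 420 may be false calls. The simulated libraries held no GC trend and used dispersions estimated by edgeR, so the share among the 420 stays unknown.

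Other splits of the same libraries were counted for each result. They exchange libraries freely, whether pools or single clones, and the 10 splits of 3 against 3 libraries are too few for a share under 0.05. For edgeR the number of splits with a count as large, the real value and the highest other were 1, 1 and 0 in O vs A, in OA vs A and in OAC vs A. They were 10, 0 and 0 in OA vs O and OAC vs OA, and 10, 0 and 1 in OAC vs O. A real count of 0 is reached by every split, so those values decide nothing. For DESeq2 they were 1, 420 and 33 in O vs A, 3, 42 and 2308 in OA vs O, 1, 130 and 69 in OA vs A, 10, 0 and 484 in OAC vs OA, 2, 101 and 1700 in OAC vs O, and 1, 57 and 36 in OAC vs A. For lists they were 2, 8 and 8 in O vs A, 4, 6 and 9 in OA vs O, 6, 4 and 8 in OA vs A, 10, 0 and 6 in OAC vs OA, 3, 5 and 7 in OAC vs O, and 4, 6 and 6 in OAC vs A. In multipotent vs unipotent 100 of 100 drawn splits gave as many edgeR genes (real 0, highest other 1), which again decides nothing. There 26 gave as many DESeq2 genes (31 and 1022) and 32 as many lists (5 and 12), so chance is not excluded for the DESeq2 genes and lists. Of the 46 of these splits with 2 pools on each side, like the real one, 9 gave as many DESeq2 genes (highest other 610) and 20 as many lists.

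The splits with the highest DESeq2 counts point to a structure of the samples. The split of OA1, OA2 and O1 from OA3, O2 and O3 called 2308 genes, that of OAC1, OAC2 and O1 from OAC3, O2 and O3 called 1700, and that of OAC1, OAC2 and OA2 from OAC3, OA1 and OA3 called 484. In the first and second splits the libraries on the first side had GC correlations of 0.09 to 0.65 and those on the other side -0.54 to -0.43. With GC factors the real splits gave 74 genes in OA vs O, 153 in OAC vs O and 2 in OAC vs OA. The other splits were not counted again with GC factors, so whether the GC trend produced their counts was not tested.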
